A study of Mus musculus with 6 samples.

How the data were processed

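RNA, surface antibody tags and hashtags were read in the same single cells on the 10x 3' platform, with 1 pool of 6 mice per week (3 young and 3 old, 12 mice in all). Per the labels' protocols, hashtags 1 to 3 marked the young and 4 to 6 the old mice of each week, lineage cells were depleted with antibodies before the sort (at week 4 also against CD11b and NK1.1), and 6000 cells were collected per mouse. The deposited matrices hold UMI counts, unique molecules per barcode and feature with no normalization, made with Cell Ranger per the file headers. The headers name version 6.0 in the matrices of called cells and Cell Ranger 4 in those of all barcodes, while the submitters' processing notes name Cell Ranger 6.0, Seurat 4.1.0 (its role is not stated) and mm10. The week 4 matrix held 13190 cell barcodes and 284526307 RNA UMIs (87.1% of those of all barcodes), the week 8 matrix 10985 barcodes and 149269887 UMIs (87.4%). Both list 32285 genes, of which 40 symbols occur more than once and were kept apart by identifier. Antibody UMIs totalled 18987859 and 16110163. CD135 has no entry in the week 8 matrix and CD199 had 0 counts in every mouse of both weeks. No feature for Tomato or Cre is listed, so the trace rests on the sort.

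Cells were assigned to mice with HTODemux of Seurat 5.3.0 at quantile 0.99, giving 11274 singlets, 1426 doublets and 490 negatives at week 4 and 9970, 874 and 141 at week 8. Cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept (10319 and 9297 singlets). Scrublet in scanpy 1.11.5, with the expected rate set from the hashtag doublets, removed a further 163 and 53 cells, leaving 10156 and 9244; it called 44.9% and 42.5% of the hashtag doublets. Where HTODemux and the ratio rule for hashtags both assigned a cell, they gave the same mouse in 10315 and 9297 cells and another in 0.

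Each week was clustered apart over both ages together: log-scaled counts per cell, 2000 variable genes, scaling, 30 principal components, a shared-neighbour graph of 20 neighbours and Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 19 and 22 clusters. Marker lists could name a cluster if their score, the mean z over the list of cluster means of log values, was at least 0.3 and at least 3 markers were found in at least 5% of its cells. Of these, the list holding most of the cluster's 10 leading genes gave the name, ties going to the higher score. Clusters stayed unnamed where another list held more leading genes, or where their median UMIs were under those of all cells divided by 3. Cluster 9 of week 8, named multipotent progenitor-like, scored higher on the HSC list (1.18 against 0.755), and cluster 13, monocyte-like, on the macrophage list (1.94 against 1.911). Cluster 10 of week 4 (549 of 1476 erythroid-like cells) held 0 erythroid leading genes and scored 0.367. The score was changed from pooled CPM to log values after the clusters had been seen, and the first form, which names cluster 14 of week 8 (296 monocyte-like cells) plasma cell-like, is among the alternatives. HSC-like cells of week 4 were led by Sult1a1, Myl10 and Nupr1 with Procr, megakaryocytic-like by Pf4 and Vwf, monocyte-like by F13a1, Ms4a6c and Irf8, multipotent progenitor-like by Adgrl4, Wfdc17 and Flt3, erythroid-like by Rhd and Car1, neutrophil-like by S100a8 and Elane, and basophil and mast-like by Prss34. At week 8 plasmacytoid dendritic-like cells were led by Siglech, Cox6a2 and Ly6d, conventional dendritic-like by H2-Aa and Cd209a or Batf3, monocyte-like by Klf4 and Lyz2, neutrophil-like by Mpo and Ctsg, multipotent progenitor-like by Ctla2a and Adgrl4, and B-lineage-like by Dntt and Ebf1. Some clusters of a class were led by cell cycle genes. The lymphoid-primed progenitor list named no cluster.

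The mouse was the replicate. Counts were summed per mouse over all cells and within each class, where a mouse entered with at least 20 cells and a class was tested with at least 2 mice of each age. Old against young was tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, two-sided) with Benjamini-Hochberg adjustment at 0.05; levels are means over mice of CPM computed from the sums. Cells per class were tested the same way with the mouse's total cells as library size, beside an exact permutation test, and antibody tags with TMM over the antibodies. The 32 gene lists, 16 of cell types and 16 of processes, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over lists with at least 3 tested members. The age effect of week 8 against week 4 was an interaction over 12 mice. Named genes were up to 8 per direction with the largest fold change among those past the threshold, at 10 CPM or more and with all old mice beyond all young mice (gene models named Gm plus digits or ending in Rik skipped), then up to 4 members of each list with the smallest p, or the 2 most abundant where none passed, and Kit, Flt3 and Pdzk1ip1. A fold against a group at 0 was taken from summed counts, against 3 counts. Coordinates are those of GRCm38 and were found by symbol for 203 of 207 named genes. H2-Q6 and H2-Q7 are near-identical copies whose counts can be shared, and their values are uncertain, as are those of histone genes.

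Depth per mouse is given in Results. Simulated counts kept genes, means and library sizes, 200 genes changing 1.5-, 2- or 4-fold. In all cells of week 4 edgeR recovered 74.6%, 80.6% and 95.5% (19 unchanged genes called). In those of week 8 it recovered 65.7%, 85.1% and 100.0% (12), in HSC-like cells 37.3%, 73.1% and 97.0% (7). Multipotent progenitor-like cells of week 8 gave 56.7%, 85.1% and 97.0% (8), and the interaction there, at 2-fold only, 63% (5).

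Alternatives were edgeR with RLE, DESeq2 1.42.0, no filter on low counts, the mouse number as a block, leaving out each mouse, a ratio rule for hashtags (top at least 3 times the second and at least 10 counts), a stricter cell filter (2000 UMIs, 5%), Scrublet-called cells kept, cells thinned to 5000 UMIs, at least 50 cells, Leiden at 0.5 and 2, clustering without the genes changed in all cells, TMM over classes, limma on centred log ratios for proteins, and camera with an estimated correlation or fry for lists. Added after the data had been seen were all-cell sums without HSC-like cells, clustering without genes changed in any class or in the HSC ageing list, naming by pooled CPM, and clustering on thinned cells. Leaving out an old mouse in basophil and mast-like cells of week 4 or B-lineage-like cells of week 8 left 1 old sample, assumed to vary like the others. Deviations of same-numbered young and old mice from their age means correlated at 0.389, 0.150 and 0.171 across genes in all cells of week 8, and at -0.15, -0.20 and 0.20 at week 4, so that the block is given beside the week 8 result, though no label pairs the mice and multipotent progenitor-like cells of week 8 gave 0.0039, -0.0054 and 0.0656; genes are not independent replicates. Week, gate, depletion and library change together, so levels were not compared between weeks. All mice of a week shared a pool and so its free RNA. Hashtag doublets and negatives were left out, and the matrices of all barcodes served only for empty droplets (5 to 50 UMIs). R 4.3.3 and Python 3.11.15 were used.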

Results

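Single-cell transcriptomes and surface proteins of haematopoietic cells descended from stem cells were compared between young (3 months) and old (20 months) female C57BL/6 mice. The mice carried Pdzk1ip1-CreER, a tamoxifen-inducible recombinase driven by a gene active in haematopoietic stem cells (HSCs), and a Tomato reporter, so that induced stem cells and their progeny were fluorescent. At 4 weeks after tamoxifen, Tomato-positive cells that lacked lineage antigens and carried cKit, a receptor of stem cells and early progenitors, were sorted. At 8 weeks the gate was instead Flt3, a receptor of multipotent and lymphoid-primed progenitors and dendritic cells. Each week had 3 young and 3 old mice, told apart by hashtag antibodies within a shared 10x pool, and 25 surface antibodies were read in the same cells. The series title names the question as how aging of stem cells relates to lymphoid development.

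At week 4, 10156 cells were used (4985 young and 5171 old, 1447 to 1903 per mouse), with 25914184 to 47254896 RNA molecules (UMIs) per mouse. At week 8 there were 9244 cells (4816 young and 4428 old, 1430 to 1743 per mouse), with 17756248 to 24051365 UMIs per mouse. Median UMIs per cell at week 4 were 19394 to 25560 in young and 13099.5 to 14818.5 in old mice. At week 8 the ages overlapped (9902 to 10855 and 9281 to 11797). Log2 fold changes in the text are old minus young and carry their SE after ±, levels are in CPM and carry their SD, and each age has 3 mice per week unless stated. Classes such as HSC-like were named from marker lists fixed before the data were examined. The 3-against-3 exact permutation tests were two-sided and could not give a p under 0.1.

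At week 4 the balance of traced cKit-positive cells differed between the ages. HSC-like cells made up 5.62% ± 1.01 in young and 30.2% ± 3.33 in old mice, a 5.38-fold higher share (log2 fold change 2.43 ± 0.23, edgeR adjusted p = 1.9e-11). Erythroid-like cells, the precursors of red cells, took 22% ± 1.67 in young and 7.30% ± 1.29 in old mice, 3.01-fold lower (-1.59 ± 0.24, adjusted p = 5.9e-07). Monocyte-like cells took 20.5% ± 2.75 in young and 7.47% ± 0.850 in old mice, 2.73-fold lower (-1.45 ± 0.25, adjusted p = 2.9e-06). In each of these classes all old mice lay beyond all young mice (exact permutation p = 0.1).

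Megakaryocytic-like cells held 21.1% ± 1.37 in young and 27.4% ± 6.36 in old mice (adjusted p = 0.10). Multipotent progenitor-like cells held 21.8% ± 3.73 in young and 18.4% ± 4.69 in old mice (adjusted p = 0.34). The neutrophil-like share was 6.08% ± 1.26 in young and 3.66% ± 1.67 in old mice (adjusted p = 0.14, and adjusted p = 0.021 without old mouse 1, with a log2 fold change of -1.13). Basophil and mast-like cells (1.75% ± 0.234 in young and 1.73% ± 0.910 in old mice, adjusted p = 0.99) and plasmacytoid dendritic-like cells (0.320% ± 0.136 and 0.364% ± 0.210, adjusted p = 0.95) were scarce. A shallow cluster left unnamed, led by Fosb, Mecom and Malat1, took 0.902% ± 0.399 in young and 3.35% ± 1.49 in old mice (adjusted p = 0.0054). It lost the call without young mouse 1 (1.56, adjusted p = 0.067) or old mouse 2 (1.77, adjusted p = 0.054), and the unnamed share turned to -1.42 when clustered on thinned cells. The HSC-like cluster was led by genes that themselves differed with age (Sult1a1, Myl10, Nupr1 and Ramp2), and clustering without the age-changed genes gave a log2 fold change of 2.37 or 2.35. The gate bears on these shares, as depth may, though UMIs per cell differed less within each tested class than over all cells.

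**Figure D1:**
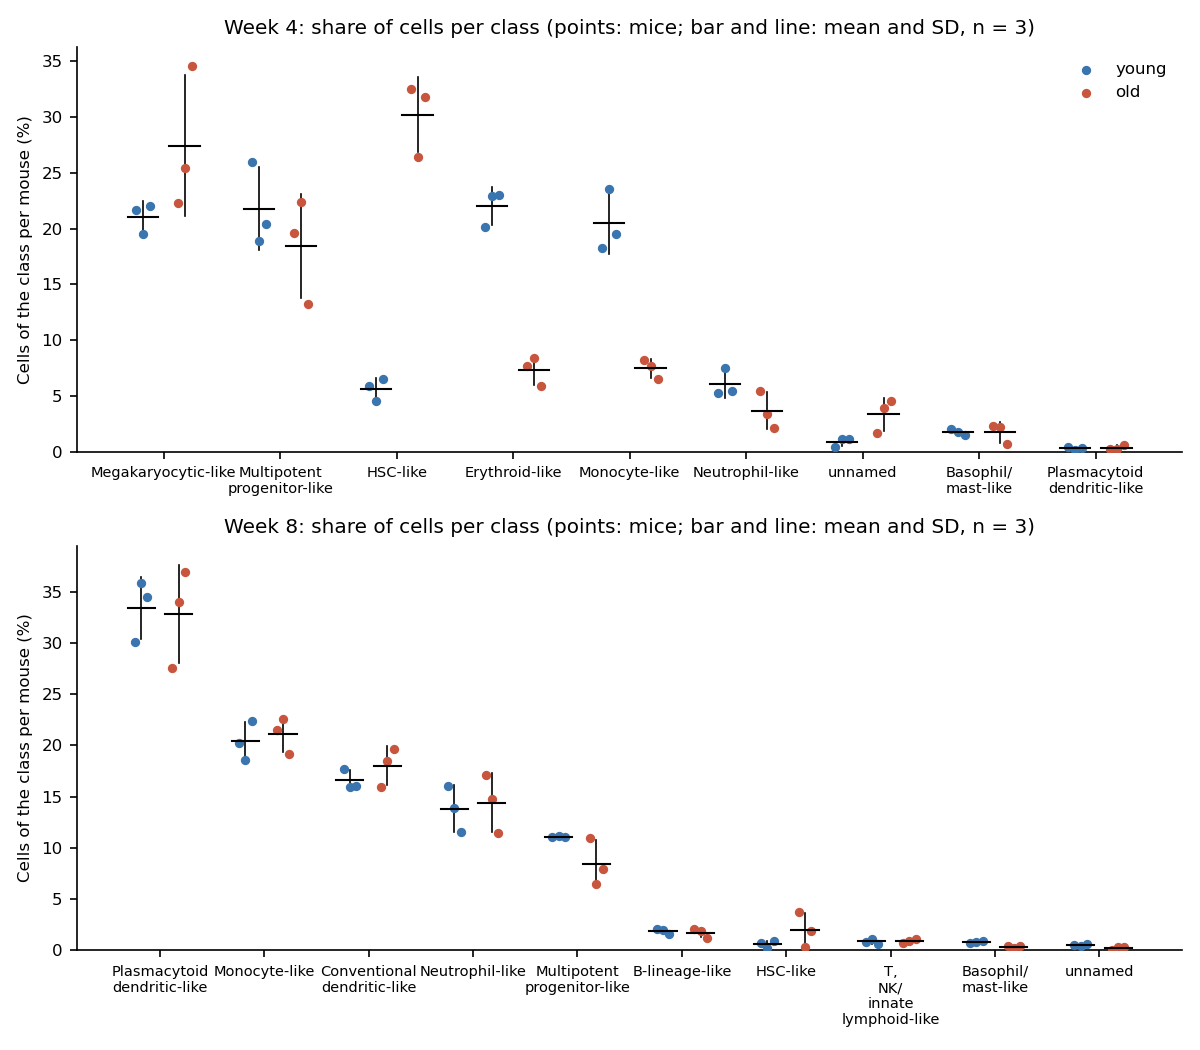
Share of each mouse's cells in each class (percent, y axis) at week 4 (top) and week 8 (bottom); points are mice, blue young and red old, bars the means and lines the SD (3 mice per age). At week 4 HSC-like cells averaged 5.62% in young and 30.2% in old mice without overlap.

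Summed over all cells of week 4, 6806 of 13586 genes differed with age (3553 higher and 3253 lower in old mice, edgeR quasi-likelihood test). Plscr2, of the phospholipid scramblase family (ENSMUSG00000032372, chromosome 9, 92275602 to 92297752, GRCm38), went from 1.64 ± 0.0758 to 30.7 ± 1.71 CPM, 18.7-fold (4.23 ± 0.08, adjusted p = 1.3e-08). Ramp2, a receptor activity-modifying protein that forms adrenomedullin receptors (ENSMUSG00000001240, chromosome 11, 101246334 to 101248250), went from 1.85 ± 0.625 to 27.7 ± 8.53 CPM (3.89 ± 0.28, adjusted p = 3.8e-05). Nupr1, a stress-induced nuclear protein (ENSMUSG00000030717, chromosome 7, 126623246 to 126625470), went from 8.17 ± 0.775 to 92.4 ± 13 CPM (3.50 ± 0.11, adjusted p = 9.6e-07). The other large increases were Sult1a1 (3.46 ± 0.15), Clec1a (3.07 ± 0.19), Iigp1 (2.86 ± 0.44), Myl10 (2.75 ± 0.27) and Npdc1 (2.47 ± 0.15), of which Iigp1 is an interferon-inducible GTPase.

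The largest decreases were smaller in size. Car1, the carbonic anhydrase of early red cells (ENSMUSG00000027556, chromosome 3, 14766214 to 14808365), went from 1060.2 ± 234 to 412 ± 43.0 CPM (-1.36 ± 0.15, adjusted p = 1.8e-04). Prss50 (-1.55 ± 0.16), Slc38a5 (-1.32 ± 0.18), Tspo2 (-1.31 ± 0.11), Atp1b2 (-1.22 ± 0.14), Sphk1 (-1.21 ± 0.16), Ermap (-1.19 ± 0.15) and Cfp (-1.18 ± 0.12) were also lower. Tspo2 and Ermap are known from erythroid cells and Cfp encodes the complement factor properdin. Of the genes behind the sort and the label, Kit was slightly higher (0.41 ± 0.05, 93.4 ± 5.17 to 124 ± 3.60 CPM, adjusted p = 2.8e-04). Pdzk1ip1 went from 23.6 ± 3.68 to 77.8 ± 6.29 CPM (1.72 ± 0.11, adjusted p = 2.3e-05), and Flt3 did not pass (-0.17 ± 0.08, adjusted p = 0.11). These sums move with the mix of classes, and without HSC-like cells, a setting chosen after seeing the data, 3510 genes passed. After thinning each cell to 5000 UMIs the count was 4377.

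Marker lists of stem, megakaryocytic, erythroid and monocytic cells changed with age. Of the HSC markers, 15 of 15 were higher (15 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 1.5e-19, adjusted p = 0.30 with an estimated correlation). Among them were Procr (2.44 ± 0.12), the endothelial protein C receptor of stem cells, and the stem cell transcription factor genes Mecom (1.70 ± 0.13) and Hlf (1.25 ± 0.09). The HSC ageing list holds genes known to rise in aged stem cells, and shares Slamf1 with the HSC list and Vwf, Cavin2 and Selp with the megakaryocytic list. Of its members 32 of 35 were higher and 1 lower (32 and 2 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 4.1e-37, adjusted p = 0.30 with an estimated correlation). Among them was Enpp5 (1.79 ± 0.10). Of the megakaryocytic markers, 9 of 13 were higher (10 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 2.8e-04, adjusted p = 0.55 with an estimated correlation). They were led by the thrombopoietin receptor gene Mpl (1.39 ± 0.14) with Selp (1.13 ± 0.12) and Cavin2 (1.10 ± 0.17). Of the erythroid markers, 13 of 16 were lower (13 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 5.0e-09, adjusted p = 0.36 with an estimated correlation). Among them were the erythroid transcription factor genes Klf1 (-0.95 ± 0.11) and Gata1 (-0.60 ± 0.06). Of the monocyte markers, 1 of 14 was higher and 9 lower (1 and 10 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 3.6e-07, adjusted p = 0.31 with an estimated correlation). Among them were Ccr2 (-1.02 ± 0.08), Ly86 (-0.96 ± 0.08), Ms4a6c (-0.83 ± 0.07) and Irf8 (-0.76 ± 0.06).

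Among neutrophil granule and precursor genes, 5 of 14 were lower (5 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.028, adjusted p = 0.65 with an estimated correlation). Among them were Prtn3 (-0.72 ± 0.17), Ctsg (-0.66 ± 0.16) and Mpo (-0.58 ± 0.14). The call was lost without young mouse 2 (adjusted p = 0.057) or old mouse 2 (adjusted p = 0.050). The multipotent progenitor list did not move as a set: 2 of 10 were higher and 3 lower (2 and 4 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.63). Angpt1 was at 0.87 ± 0.10 and Cd48 at -0.69 ± 0.14. Myeloid growth factor receptors and regulators were lower: 10 of 19 were lower (10 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0012, adjusted p = 0.55 with an estimated correlation). Among them were Csf1r (-0.81 ± 0.12) and Il6ra (-0.45 ± 0.06). Basophil and mast markers had a positive median and a negative mean (0.28 and -0.06, camera adjusted p = 0.76). The basophil protease gene Prss34 was lower (-2.20 ± 0.48), a direction that turned under the ratio rule for hashtags (0.13). Conventional dendritic markers divided: 6 of 10 were higher and 2 lower (6 and 3 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.28). H2-Aa and Cadm1 were higher (1.90 ± 0.27 and 1.79 ± 0.31) and Clec10a lower (-0.80 ± 0.14). Without young mouse 2 the list passed (adjusted p = 0.0049).

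Several other cell type lists did not pass. Of the plasmacytoid dendritic markers, 3 of 11 were higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.92), camera's direction being down against the median. Of the macrophage markers, 1 of 6 was lower (1 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.52). Of the plasma cell markers, 1 of 5 was lower (1 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.14), namely Ighm (-0.94 ± 0.07). Of the stromal and endothelial markers, 3 of 5 were higher (3 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 0.065). Among them were Emcn (1.54 ± 0.19), Col1a2 (1.23 ± 0.17) and Kdr (1.03 ± 0.16). The list passed without young mouse 3 (adjusted p = 0.045). None of the 4 eosinophil markers passed (median -0.18, camera adjusted p = 0.76).

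Lymphoid genes went both ways. Of the lymphoid-primed progenitor markers, 3 of 13 were higher and 2 lower (3 and 2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.93). The cytokine gene Ltb was higher (1.5 ± 0.14), and the homing receptor and lymphoid regulator genes Sell and Ikzf1 were lower (-0.58 ± 0.08 and -0.38 ± 0.05). Of the lymphoid transcription regulators, 14 of 21 were higher and 2 lower (15 and 3 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 5.3e-04, adjusted p = 0.30 with an estimated correlation). Among them were Rorc (3.45 ± 0.21), Rora (1.71 ± 0.15) and Ets1 (1.06 ± 0.12). Of the T, NK and innate lymphoid markers, 4 of 6 were higher (4 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 0.042, adjusted p = 0.52 with an estimated correlation). Among them were Gata3 (1.70 ± 0.17) and Klrb1c (1.02 ± 0.20). It was lost without young mouse 2, young mouse 3, old mouse 1 or old mouse 2 (adjusted p = 0.12, 0.062, 0.12 and 0.19). Of the B-lineage markers, 1 of 7 was higher (0 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.64). Of the cytokine receptors of lymphoid progenitors, 5 of 12 were higher and 2 lower (5 and 2 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.48). Of the genes of V(D)J recombination and the surrogate light chain, 1 of 11 was higher and 2 lower (1 and 2 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.68).

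Lists of interferon response, MHC, immediate early, NF-kappaB and p53 genes were higher in old mice. Of the interferon response genes, 24 of 33 were higher (28 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 1.9e-05, adjusted p = 0.63 with an estimated correlation). Among them were Ifit3 (2.32 ± 0.34), Ifit1 (2.07 ± 0.25) and Gbp2 (1.20 ± 0.12). Of the MHC class I genes, 9 of 14 were higher (9 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 4.0e-04, adjusted p = 0.55 with an estimated correlation). Of the immediate early and stress genes, 18 of 26 were higher and 1 lower (19 and 1 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 5.0e-09, adjusted p = 0.32 with an estimated correlation). Among them were Klf2 (2.12 ± 0.11), Fosb (1.40 ± 0.13), Fos (1.34 ± 0.09) and Zfp36 (1.11 ± 0.10). Median mitochondrial percent was also higher in old mice at this week (2.05 to 2.14 against 1.74 to 1.79), whereas at week 8 the ages overlapped. Of the NF-kappaB targets, 7 of 18 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.041, adjusted p = 0.63 with an estimated correlation). Its call ended without young mouse 3, old mouse 1 or old mouse 2 (adjusted p = 0.10, 0.066 and 0.088). Of the p53 target and senescence genes, 10 of 18 were higher and 2 lower (10 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.014, adjusted p = 0.53 with an estimated correlation). Among them were Plk2 (2.83 ± 0.16), Perp (1.29 ± 0.20) and Cdkn2c (0.67 ± 0.07). That call was lost without old mouse 1 (adjusted p = 0.058). Of the MHC class II genes, 6 of 10 were higher (6 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0496, adjusted p = 0.63 with an estimated correlation). The list lost its call without young mouse 1, young mouse 3 or old mouse 2 (adjusted p = 0.076, 0.088 and 0.18).

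Over all cells, whose class mix differed, cell cycle and ribosome biogenesis lists were lower in old mice at week 4. Of these only G2 and M phase passed within HSC-like cells. Of the S phase genes, 39 of 41 were lower (39 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 1.5e-16, adjusted p = 0.30 with an estimated correlation). Among them were Mcm5 (-0.42 ± 0.04), Mcm6 (-0.40 ± 0.03) and Mcm7 (-0.41 ± 0.04). Of the G2 and M phase genes, 1 of 52 was higher and 32 lower (1 and 36 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 4.2e-06, adjusted p = 0.63 with an estimated correlation). Among them were Tacc3 (-0.41 ± 0.07) and Hmgb2 (-0.38 ± 0.06). Of the ribosome biogenesis and MYC target genes, 1 of 34 was higher and 32 lower (1 and 32 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 8.4e-13, adjusted p = 0.46 with an estimated correlation). Among them were Npm1 (-0.38 ± 0.03) and Ncl (-0.38 ± 0.04). Of the unfolded protein response genes, 2 of 21 were higher and 12 lower (2 and 14 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.041, adjusted p = 0.72 with an estimated correlation). Pdia6 was lower (-0.38 ± 0.07) and Trib3 higher (1.73 ± 0.22). The call was lost without young mouse 2, old mouse 2 or old mouse 3 (adjusted p = 0.057, 0.050 and 0.068). Mitochondrially encoded genes divided: 6 of 13 were higher and 4 lower (6 and 4 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.74). mt-Co1 was at 0.29 ± 0.03. Of the 32 lists, 19 passed with a preset correlation (11 up, 8 down) and 0 with an estimated correlation, and fry called 19, of which 15 were among those of camera.

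Within HSC-like cells of week 4 (278 young and 1561 old, 78 to 618 per mouse), which ask whether the stem cells themselves differed, 156 of 10461 genes passed (103 higher and 53 lower in old mice). Gpr183, a receptor for oxysterols that guides immune cells (ENSMUSG00000051212, chromosome 14, 121952331 to 121965193), had no count in any young mouse and 27.2 ± 15.1 CPM in old mice, at least 26.3-fold higher. Mab21l2 was likewise at 0 in young and 22.9 ± 8.21 CPM in old mice, at least 21.0-fold higher, both from summed counts against a floor of 3 over the young group. Plscr2 went from 6.33 ± 2.64 to 87.2 ± 11.2 CPM (3.72 ± 0.24, adjusted p = 1.6e-10) and Nupr1 from 45.0 ± 7.24 to 360.4 ± 47.3 CPM (2.99 ± 0.13, adjusted p = 6.1e-14). The metallothionein genes Mt2 (3.18 ± 0.34) and Mt1 (1.74 ± 0.11), which bind metal ions, were higher too, as were Sbspon (3.07 ± 0.37), Rorb (2.39 ± 0.28) and Ramp2 (2.24 ± 0.23). Nupr1 and Ramp2 are also leading genes of the cluster that makes up this class.

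Lower in old HSC-like cells were Shisa8 (-2.14 ± 0.26, 21.4 ± 4.09 to 4.92 ± 0.104 CPM, adjusted p = 1.5e-05) and the stem cell transcription factor gene Hlf (-0.76 ± 0.08, 405 ± 57.0 to 238 ± 0.534 CPM, adjusted p = 1.9e-06). So were Fscn1 (-1.73 ± 0.29), Arhgap30 (-1.36 ± 0.21), Mgst1 (-1.34 ± 0.22) and Ebi3 (-1.30 ± 0.21). The RNA-binding protein gene Igf2bp2, known from foetal and juvenile stem cells, was at -2.04 ± 0.35 and lost its call without young mouse 3 (adjusted p = 0.080). Wfdc17 (-2.09 ± 0.35) lost it without young mouse 1 (adjusted p = 0.059), and Pole (-1.29 ± 0.28) without young mouse 1 or 2 (adjusted p = 0.29 and 0.091). Kit (-0.08 ± 0.07, adjusted p = 0.77), Flt3 (-1.88 ± 0.55, adjusted p = 0.096) and Pdzk1ip1 (0.29 ± 0.08, adjusted p = 0.080) did not pass. Pdzk1ip1 passed without old mouse 3 (adjusted p = 0.041). The count of changed genes was 98 without young mouse 1, 83 without young mouse 2 and 103 without young mouse 3. It was 1246 under the ratio rule for hashtags (608 higher, 638 lower), 1236 with Scrublet-called cells kept (583 higher, 653 lower), 55 under the stricter cell filter and 102 after thinning. All of these move cells in or out of the class or its sums.

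**Figure D2:**
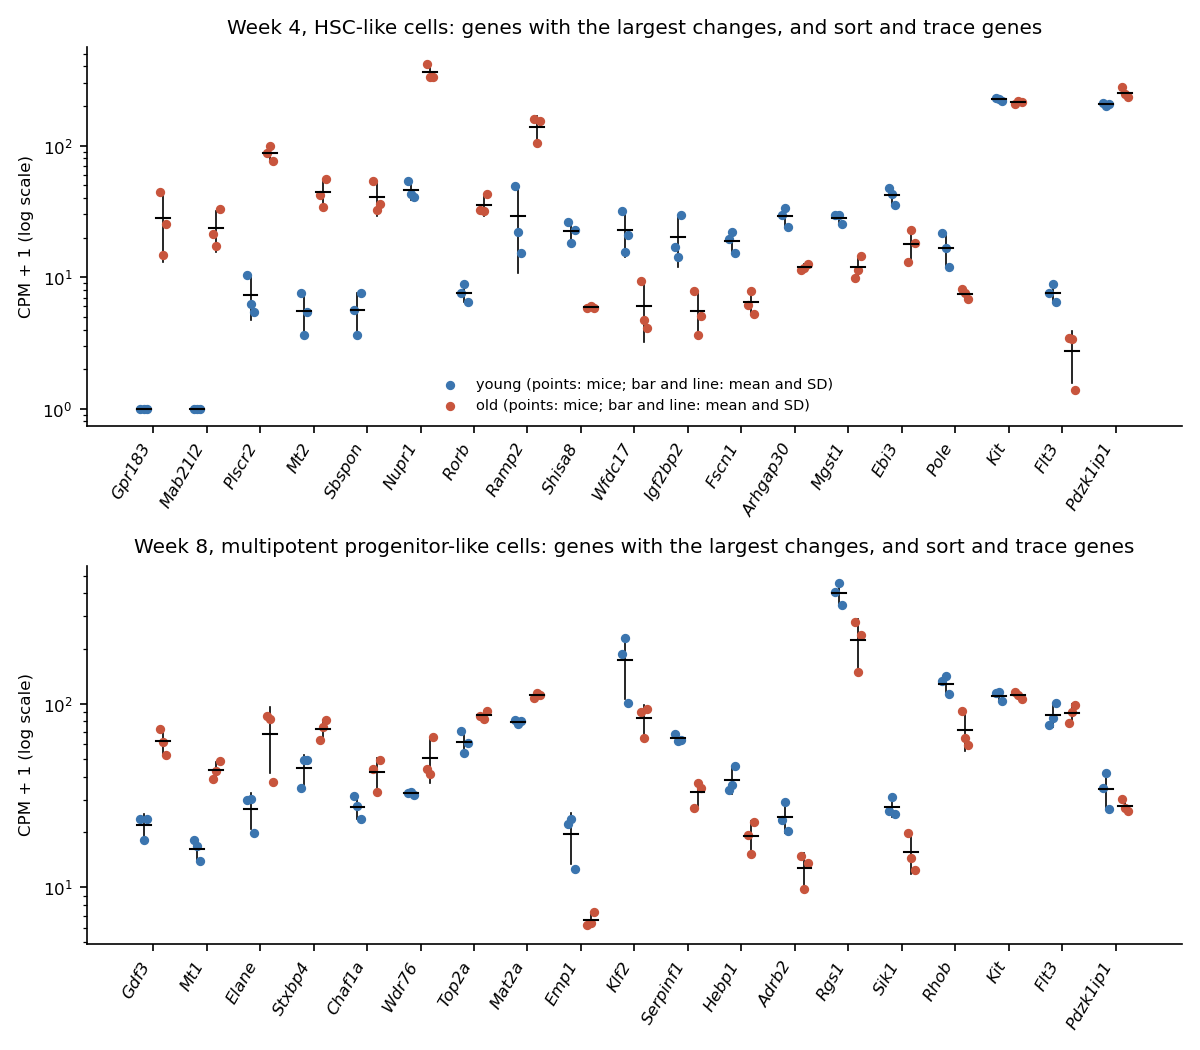
Level of the genes with the largest age changes, and of Kit, Flt3 and Pdzk1ip1, in HSC-like cells of week 4 (top) and multipotent progenitor-like cells of week 8 (bottom), as CPM plus 1 on a log scale (y axis); points are mice (blue young, red old), bars means and lines SD, 3 mice per age. Nupr1 averaged 45.0 CPM in young and 360.4 in old HSC-like cells, whereas Kit averaged 225 and 213.

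The HSC ageing list moved most within HSC-like cells: 18 of 32 were higher (27 adjusted over the list alone), with a median of 0.99 (camera adjusted p = 1.1e-98, and adjusted p = 0.031 with an estimated correlation). The megakaryocytic list shares genes with it. Of the megakaryocytic markers, 2 of 10 were higher (3 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 1.3e-05, adjusted p = 0.24 with an estimated correlation). Of the interferon response genes, 2 of 31 were higher (7 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 4.1e-11, adjusted p = 0.36 with an estimated correlation). Of the immediate early and stress genes, 5 of 21 were higher (9 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 2.9e-09, adjusted p = 0.25 with an estimated correlation). Of the MHC class I genes, 3 of 14 were higher (4 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 3.9e-05, adjusted p = 0.36 with an estimated correlation). Of the unfolded protein response genes, 1 of 21 was higher and 0 lower (7 and 1 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 4.1e-05, adjusted p = 0.36 with an estimated correlation). Of the mitochondrially encoded genes, 1 of 13 was higher (5 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 1.4e-04, adjusted p = 0.36 with an estimated correlation). Of the p53 target and senescence genes, 1 of 14 was higher (3 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0033, adjusted p = 0.36 with an estimated correlation). The member was the cell cycle inhibitor gene Cdkn2c (1.51 ± 0.23). It was lost without young mouse 1, young mouse 3 or old mouse 1 (adjusted p = 0.065, 0.058 and 0.12).

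Few progenitor and lymphoid-primed markers passed within HSC-like cells. Of the lymphoid-primed progenitor markers, 1 of 8 was lower (3 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.6e-06, adjusted p = 0.079 with an estimated correlation). Ltb was at -0.62 ± 0.12 (195 ± 13.5 to 128 ± 25.6 CPM, adjusted p = 0.0031), and its call was lost without young mouse 3 (adjusted p = 0.053). Of the multipotent progenitor markers, 1 of 10 was lower (2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 1.6e-05, adjusted p = 0.24 with an estimated correlation). Sox4 (-0.45 ± 0.09), the member that passed, lost its call without young mouse 1 or 2 (adjusted p = 0.12 and 0.10) and turned under the stricter cell filter (0.08). Of the cytokine receptors of lymphoid progenitors, none passed over all genes and 1 of 9 was lower adjusted over the list alone (median -0.14, camera adjusted p = 0.031, adjusted p = 0.36 with an estimated correlation). Its call ended when any mouse of the 6 was left out (adjusted p from 0.051 to 0.37). Of the G2 and M phase genes, 1 of 37 was higher and 1 lower (1 and 4 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.039, adjusted p = 0.36 with an estimated correlation). That call was lost without young mouse 1, young mouse 3, old mouse 1 or old mouse 3 (adjusted p = 0.36, 0.29, 0.18 and 0.13). The HSC list did not move as a set: 1 of 15 was higher and 2 lower (5 and 4 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.56). Hlf and Mllt3 were lower, Mllt3 at -0.51 ± 0.09, which turned to 0.05 both under the ratio rule and with Scrublet-called cells kept. The list's median and mean (-0.01) differed in sign. S phase genes (median -0.12, camera adjusted p = 0.21), ribosome biogenesis and MYC targets (median 0.00, camera adjusted p = 0.99) and lymphoid transcription regulators (median 0.13, camera adjusted p = 0.80) did not pass. Of 27 lists, 12 passed with the preset correlation, 1 with an estimated correlation (HSC ageing) and 2 by fry (HSC ageing and lymphoid-primed progenitor, both adjusted p = 0.028).

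**Figure D3:**
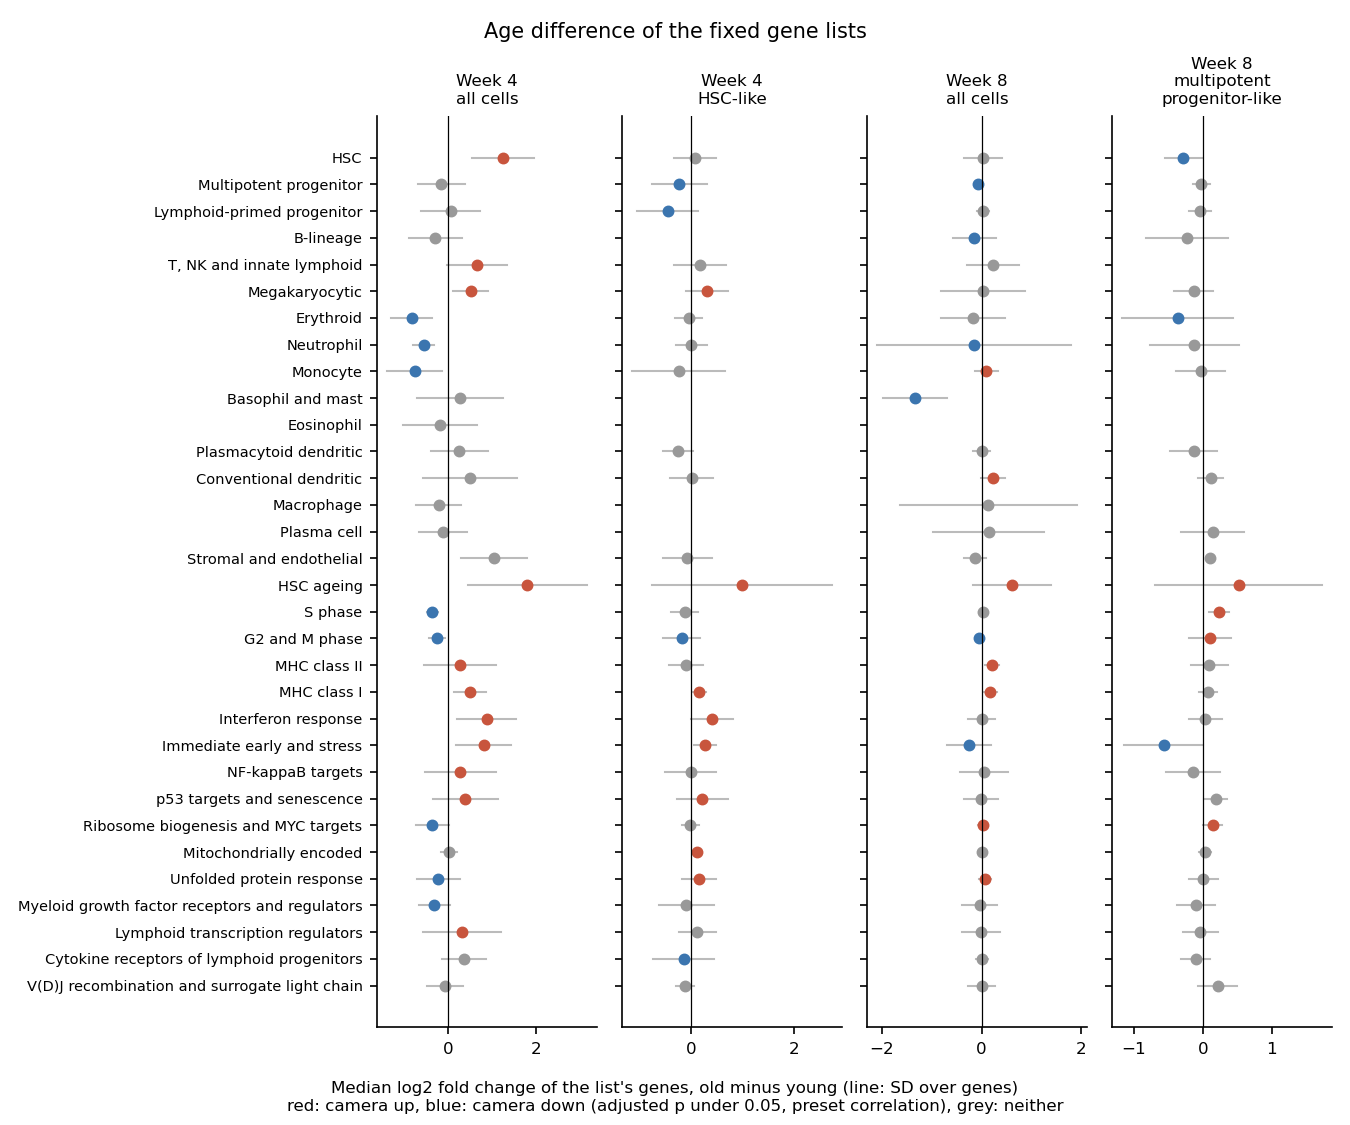
Median log2 fold change with age (old minus young, x axis) of each gene list (y axis) in 4 comparisons; lines are the SD over a list's genes, red and blue mark lists called up and down by camera with the preset correlation (adjusted p under 0.05) and grey the rest, and a list with too few tested genes is left out. The HSC ageing list lies at 1.79 in all cells and 0.99 in HSC-like cells of week 4, and the immediate early and stress list at 0.81 in all cells of week 4 and -0.57 in multipotent progenitor-like cells of week 8.

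Over all cells of week 4, whose class mix differed, 13 of the 26 antibodies and controls that gave counts passed. Stem cell antigens were higher in old mice: CD150, the product of Slamf1, went from 21.4 ± 1.06 to 48.6 ± 7.04 tags per cell (1.35 ± 0.17, edgeR adjusted p = 5.5e-04). CD201, the product of Procr, went from 2.09 ± 0.0983 to 5.78 ± 0.680 tags per cell (1.63 ± 0.21). CD41 (1.24 ± 0.18), the integrin of megakaryocytic cells, and Sca-1 (1.48 ± 0.26) were higher as well. CD71, the transferrin receptor of erythroid cells, went from 72.9 ± 20.6 to 27.3 ± 5.15 tags per cell (-1.25 ± 0.21). CD48, an antigen lost from stem cells, went from 187 ± 29.3 to 89.8 ± 20.2 tags per cell (-0.90 ± 0.17). CD115 (-1.26 ± 0.20), CD16/32 (-1.19 ± 0.20), CD62L (-0.94 ± 0.13) and Ly6C (-0.68 ± 0.15) were lower.

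CD14 (0.90 ± 0.25), CD127 (0.67 ± 0.18) and NK1.1 (1.01 ± 0.35), the last of which was also a target of the depletion, were higher but depended on single mice. CD14 lost its call without young mouse 3 (adjusted p = 0.058), CD127 without old mouse 1 or 2 (adjusted p = 0.12 and 0.11), and NK1.1 without young mouse 3, old mouse 1 or old mouse 2 (adjusted p = 0.084, 0.12 and 0.17). CD127 had fewer tags per cell (0.235 and 0.338) than the isotype control (0.481 and 0.664), and limma did not call it (adjusted p = 0.47). CD117, the sorted cKit protein, was close in both ages after scaling (0.01 ± 0.10, adjusted p = 0.94). CD135 (Flt3) was at 0.87 ± 0.37 (adjusted p = 0.073), and the isotype control was at 0.60 ± 0.24 (adjusted p = 0.067). Without young mouse 1 or old mouse 3, CD135 passed (adjusted p = 0.0024 and 0.0088), and so did the isotype control (adjusted p = 0.0030 and 0.0087). Within HSC-like cells edgeR called 0 proteins, 8 having an unadjusted p under 0.05, and limma called 3 (CD150, CD41 and CD16/32). There CD150 lay at 0.32, CD41 at 0.66, CD201 at 0.18 and Sca-1 at -0.06. Without young mouse 1 edgeR called 7 and without old mouse 3 it called 4.

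**Figure D4:**
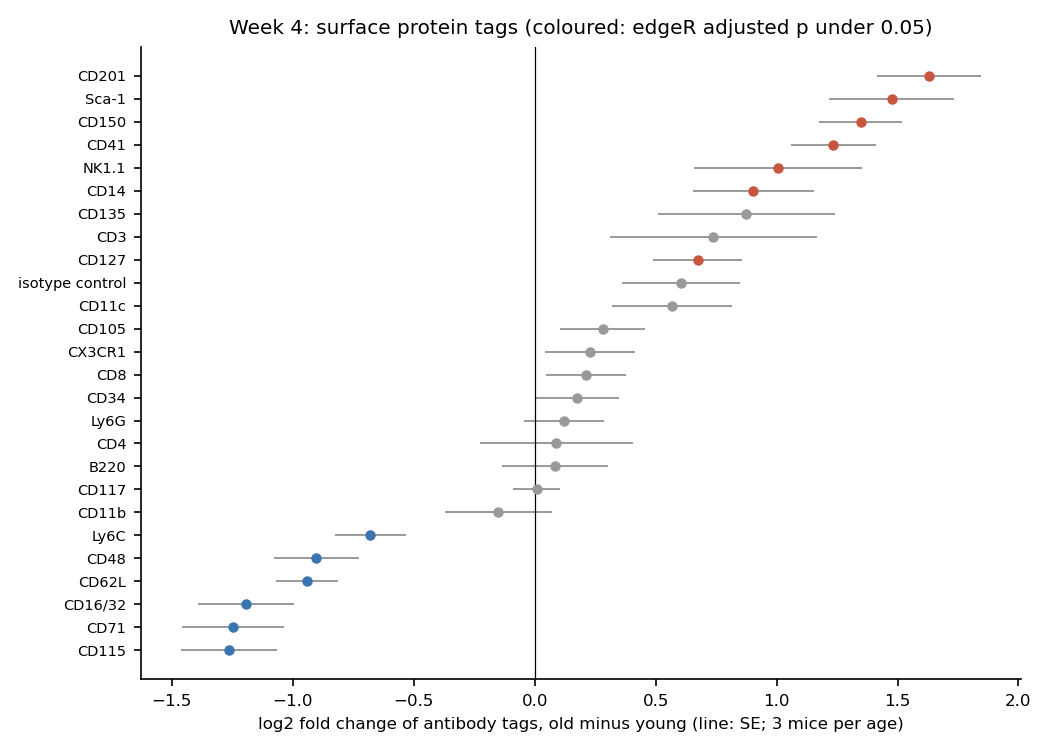
Log2 fold change of antibody tags summed over all cells of week 4 (old minus young, x axis) for each antibody (y axis); lines are SE, 3 mice per age, and red (higher) and blue (lower) mark edgeR adjusted p under 0.05. CD201 lies highest at 1.63 and CD115 lowest at -1.26, while the sorted CD117 lies at 0.01.

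Other classes of week 4 differed widely in how many genes changed. In megakaryocytic-like cells 1035 of 11258 genes passed (611 higher, 424 lower), with 529 without young mouse 2, 592 without young mouse 3, 514 by DESeq2, 357 after thinning and 229 when clustered on thinned cells. The cluster holding the most cells of the class was cluster 4 in young mice (36.8%) and cluster 2 in old mice (43.9%). In monocyte-like cells 107 of 10537 genes passed (68 higher, 39 lower), and DESeq2 called 22 higher and 72 lower. Counts were 43 without young mouse 1, 42 without young mouse 2, 209 without young mouse 3, 65 without old mouse 1 and 15 without old mouse 2. In multipotent progenitor-like cells 63 of 11083 genes passed (43 higher, 20 lower), with 39 without young mouse 2, 41 without young mouse 3, 108 without old mouse 1, 26 without old mouse 2, 121 under the ratio rule, 113 with the mouse number as a block, 126 and 115 when clustered without genes changed in all cells or in any class, and 238 with no filter. The fullest cluster of the class was cluster 8 in young and cluster 5 in old mice. In neutrophil-like cells 52 of 9063 genes passed (32 higher, 20 lower), DESeq2 calling 8 higher and 25 lower, with 30 without young mouse 2, 20 without old mouse 2, 29 without old mouse 3, 158 at the lower Leiden resolution, 11 when clustered without genes changed in all cells and 9 after thinning. In basophil and mast-like cells (3 young and 2 old mice) 38 of 6040 genes passed (17 higher, 21 lower), with 14 without young mouse 1, 59 without young mouse 2 and 119 without old mouse 2. In erythroid-like cells edgeR called 0 of 10092 genes, 522 having an unadjusted p under 0.05, and DESeq2 called 6. The edgeR count was 41 without young mouse 1, 1 without young mouse 3, 1 without old mouse 1 and 1 without old mouse 2. Plasmacytoid dendritic-like cells were too few to test.

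At week 8, in the Flt3 gate, edgeR called 0 of 9 named classes as changed in share, 1 having an unadjusted p under 0.05 and 2 reaching the smallest exact permutation p of 0.1. Plasmacytoid dendritic-like cells were the largest class with 33.5% ± 3.01 in young and 32.9% ± 4.78 in old mice. Monocyte-like (20.4% ± 1.90 and 21.1% ± 1.74), conventional dendritic-like (16.6% ± 0.993 and 18.0% ± 1.90) and neutrophil-like cells (13.8% ± 2.27 and 14.4% ± 2.86) followed. Multipotent progenitor-like cells took 11.1% ± 0.0548 and 8.44% ± 2.28 (-0.39 ± 0.21, adjusted p = 0.23). HSC-like cells took 0.619% ± 0.316 and 1.96% ± 1.72 (1.65 ± 0.75, adjusted p = 0.23). Plasmacytoid clusters 6, 8 and 16, not 2, 11 and 12, scored second on the lymphoid-primed list (0.591 against 0.84 in cluster 8, led by Ly6d with Il7r).

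B-lineage-like (1.88% ± 0.268 in young and 1.71% ± 0.456 in old mice, adjusted p = 0.85), T, NK and innate lymphoid-like (0.853% ± 0.226 and 0.909% ± 0.207, adjusted p = 0.85) and basophil and mast-like cells (0.794% ± 0.0912 and 0.338% ± 0.113, adjusted p = 0.11) were scarce. A cluster of interferon-responsive cells left unnamed, led by Isg15 and Usp18, held 0.498% ± 0.102 in young and 0.254% ± 0.165 in old mice (adjusted p = 0.23). Without old mouse 1 the multipotent progenitor-like share passed (log2 fold change -0.62, adjusted p = 0.031), and without old mouse 2 the HSC-like share passed (2.17, adjusted p = 0.0019). With the mouse number as a block the HSC-like share also passed (1.63, adjusted p = 0.0044).

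No cluster of week 8 was named lymphoid-primed progenitor-like, the class the design had set for this week. The 3 alternatives that gave such a class drew it from different cells: by their main names 555 of 726 and 345 of 519 were plasmacytoid dendritic-like, and 159 of 202 B-lineage-like. It held 726 cells at the lower Leiden resolution (7.95% ± 0.594 in young and 7.68% ± 1.57 in old mice, exact permutation p = 0.8). It held 519 when clustered without age-changed genes (5.54% ± 0.203 and 5.65% ± 1.28, exact permutation p = 1), and 202 when clustered on thinned cells (2.48% ± 0.214 and 1.99% ± 0.537, exact permutation p = 0.3). Within these classes edgeR called 6, 8 and 0 genes (447, 395 and 121 at an unadjusted p under 0.05). The multipotent progenitor-like class was chosen in its place after the values were seen.

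Summed over all cells of week 8, 5 of 12635 genes passed. Gdf3, a growth factor of the TGF-beta family (ENSMUSG00000030117, chromosome 6, 122605403 to 122610087), went from 9.22 ± 0.208 to 27.3 ± 3.94 CPM (1.57 ± 0.11, adjusted p = 0.0018) and kept its call without each mouse in turn. Tnfsf13, which encodes the B-cell survival cytokine APRIL, went from 32.1 ± 1.79 to 46.5 ± 1.86 CPM (0.53 ± 0.06, adjusted p = 0.023). AW112010 went from 58.7 ± 1.55 to 79.7 ± 4.75 CPM (0.44 ± 0.05, adjusted p = 0.045). Emp1, an epithelial membrane protein gene (ENSMUSG00000030208, chromosome 6, 135362550 to 135383173), went from 36.2 ± 6.06 to 16.7 ± 0.670 CPM (-1.11 ± 0.11, adjusted p = 0.023). Pink1, a mitochondrial kinase gene, went from 46.2 ± 0.899 to 36.0 ± 0.616 CPM (-0.36 ± 0.04, adjusted p = 0.045). Flt3 (-0.02 ± 0.05), Kit (-0.08 ± 0.10) and Pdzk1ip1 (0.53 ± 0.40) did not pass (adjusted p = 0.99, 0.98 and 0.95).

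The count of changed genes at week 8 was 1 without young mouse 1, 2 without young mouse 3, 43 without old mouse 1, 10 without old mouse 2 and 3 without old mouse 3. With the mouse number as a block it was 27. Without young mouse 1, Emp1 (adjusted p = 0.16), Tnfsf13 (adjusted p = 0.22), AW112010 (adjusted p = 0.29) and Pink1 (adjusted p = 0.42) lost their calls. Without old mouse 3 the same genes lost theirs (adjusted p = 0.055 for Emp1, 0.055 for Tnfsf13, 0.055 for AW112010 and 0.067 for Pink1). Tnfsf13 also lost its call without young mouse 2, young mouse 3 or old mouse 2 (adjusted p = 0.062, 0.15 and 0.055), AW112010 without young mouse 2 or 3 (adjusted p = 0.21 and 0.26), and Pink1 without young mouse 2, young mouse 3 or old mouse 2 (adjusted p = 0.21, 0.26 and 0.11). DESeq2 called 33 genes, and edgeR on thinned cells called 0.

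In all cells of week 8 no list member passed over all genes. The HSC ageing list was higher (8 higher and 0 lower of 24 adjusted over the list alone, median 0.60, camera adjusted p = 1.3e-17, adjusted p = 0.25 with an estimated correlation). So were MHC class I genes (8 higher and 0 lower of 14 adjusted over the list alone, median 0.18, camera adjusted p = 3.6e-11, adjusted p = 0.26 with an estimated correlation). Basophil and mast markers were lower (0 higher and 4 lower of 8 adjusted over the list alone, median -1.34, camera adjusted p = 1.5e-16, adjusted p = 0.25 with an estimated correlation). So were the neutrophil markers (1 higher and 6 lower of 15 adjusted over the list alone, median -0.15, camera adjusted p = 5.9e-08, adjusted p = 0.37 with an estimated correlation, mean -1.49). Immediate early and stress genes were lower (3 higher and 11 lower of 25 adjusted over the list alone, median -0.26, camera adjusted p = 7.5e-12, adjusted p = 0.26 with an estimated correlation). Fos was at -0.94 ± 0.28, from 1148 ± 329 to 596 ± 247 CPM. Without old mouse 1 Fos passed (adjusted p = 0.044). The lymphoid-primed progenitor list (median 0.03, camera adjusted p = 0.99), lymphoid transcription regulators (median -0.01, camera adjusted p = 0.47) and V(D)J recombination genes (median 0.00, camera adjusted p = 0.71) did not pass. Dntt, the lymphoid terminal transferase gene, was at -0.24 ± 0.12 and Lsp1 at -0.02 ± 0.07. Without old mouse 3 the lymphoid transcription regulators passed (adjusted p = 0.039).

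The remaining lists that passed at week 8 had no member past the threshold adjusted over the list alone, and lost their calls without single mice. These were conventional dendritic markers (15 tested, median 0.23, camera adjusted p = 0.015, adjusted p = 0.82 with an estimated correlation), lost without young mouse 2, old mouse 2 or old mouse 3 (adjusted p = 0.23, 0.45 and 0.96). Monocyte markers (14 tested, median 0.10, camera adjusted p = 0.016, adjusted p = 0.82 with an estimated correlation) were lost without young mouse 2, old mouse 2 or old mouse 3 (adjusted p = 0.12, 0.86 and 0.067). MHC class II genes (10 tested, median 0.21, camera adjusted p = 0.035, adjusted p = 0.82 with an estimated correlation) were lost without young mouse 2, old mouse 2 or old mouse 3 (adjusted p = 0.28, 0.31 and 0.91). Unfolded protein response genes (21 tested, median 0.06, camera adjusted p = 0.017, adjusted p = 0.82 with an estimated correlation) were lost without young mouse 3, old mouse 2 or old mouse 3 (adjusted p = 0.055, 0.26 and 0.093). Multipotent progenitor markers (10 tested, median -0.07, camera adjusted p = 0.017, adjusted p = 0.39 with an estimated correlation) were lost without young mouse 1, young mouse 2, old mouse 2 or old mouse 3 (adjusted p = 0.062, 0.095, 0.21 and 0.067). B-lineage markers (11 tested, median -0.15, camera adjusted p = 0.026, adjusted p = 0.47 with an estimated correlation) were lost without young mouse 2, young mouse 3, old mouse 1 or old mouse 3 (adjusted p = 0.10, 0.49, 0.099 and 0.16). G2 and M phase genes (52 tested, median -0.04, camera adjusted p = 0.015, adjusted p = 0.97 with an estimated correlation) were lost without young mouse 2 (adjusted p = 0.25) and turned without old mouse 3 (adjusted p = 4.1e-04). Ribosome biogenesis and MYC targets (34 tested, median 0.03, camera adjusted p = 0.043, adjusted p = 0.95 with an estimated correlation) were lost without young mouse 2 or young mouse 3 (adjusted p = 0.23 and 0.14), turned without old mouse 1 (adjusted p = 0.84) and were lost with the mouse number as a block (adjusted p = 0.055). Of 31 lists 13 passed with the preset correlation, and 0 did with an estimated correlation or by fry. Without young mouse 2 camera called 6.

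Within multipotent progenitor-like cells of week 8 (533 young and 377 old), 61 of 9681 genes passed (33 higher and 28 lower in old mice). Gdf3 went from 20.7 ± 3.21 to 61.5 ± 10.3 CPM (1.59 ± 0.15, adjusted p = 9.3e-08) and Plscr2 from 2.05 ± 1.77 to 15.2 ± 4.13 CPM (2.75 ± 0.38, adjusted p = 7.6e-05). Mt1 (1.45 ± 0.16) and Stxbp4 (0.72 ± 0.13) were higher. The immediate early transcription factor gene Fos went from 1399.6 ± 601 to 508 ± 241 CPM (-1.43 ± 0.21, adjusted p = 1.3e-04). Rgs1, a regulator of G protein signalling, went from 402 ± 53.8 to 220.3 ± 66.8 CPM (-0.83 ± 0.11, adjusted p = 5.8e-05). Emp1 (-1.73 ± 0.28), Serpinf1 (-1.04 ± 0.13), Hebp1 (-1.03 ± 0.17), Rhob (-0.80 ± 0.11) and Jund (-0.63 ± 0.09) were lower too, as was Hlf (-0.79 ± 0.11, 184 ± 1.46 to 107 ± 30.5 CPM, adjusted p = 4.6e-05).

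The replication genes Top2a (0.49 ± 0.11) and Mcm5 (0.42 ± 0.09) were higher but lost their calls without young mouse 2 (adjusted p = 0.26 and 0.22) or old mouse 3 (adjusted p = 0.11 and 0.11), Mcm5 also without old mouse 1 (adjusted p = 0.080). The neutrophil elastase gene Elane was higher (1.42 ± 0.20) and turned when clustered without the genes changed in any class (-0.58). Its levels (25.6 and 67.8 CPM) lay under that of the pool's empty droplets (395.6 CPM), as did those of Mt1 (94.2 CPM) and Klf2 (377.4 CPM). Klf2, a quiescence-linked factor, was lower (-1.04 ± 0.17) but not past the threshold without young mouse 2 (adjusted p = 0.063). Flt3 (0.02 ± 0.11), Kit (0.01 ± 0.08), Pdzk1ip1 (-0.30 ± 0.16) and the lymphoid genes Dntt (0.26 ± 0.16) and Lsp1 (-0.08 ± 0.07) did not pass (adjusted p = 0.97, 0.98, 0.55, 0.63 and 0.74). Dntt passed without young mouse 3 (log2 fold change 0.65, adjusted p = 0.0014). The count of changed genes was 20 without young mouse 2, 99 without young mouse 3 and 33 without old mouse 3, and DESeq2 called 27 (22 higher, 5 lower), Fos, Rgs1 and Jund not among them. It was 26 under the stricter cell filter (6 higher, 20 lower), 39 after thinning (14 and 25), 33 when clustered on thinned cells (11 and 22) and 51 when clustered without genes changed in any class (15 and 36). Cluster 9 held most of the class in young mice (54.2%) and cluster 10 in old mice (54.9%).

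Of the immediate early and stress genes in this class, 2 of 22 were higher and 11 lower (2 and 17 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 2.9e-28, adjusted p = 0.15 with an estimated correlation). Of the S phase genes, 3 of 41 were higher (15 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 1.6e-18, adjusted p = 0.18 with an estimated correlation). Of the ribosome biogenesis and MYC targets, 1 of 34 was higher (9 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 5.1e-08, adjusted p = 0.30 with an estimated correlation). Of the G2 and M phase genes, 1 of 45 was higher (5 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 4.4e-05, adjusted p = 0.34 with an estimated correlation). Of the HSC ageing genes, 3 of 10 were higher (5 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 2.7e-07, adjusted p = 0.15 with an estimated correlation). Of the HSC markers, 1 of 10 was lower (2 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 2.0e-06, adjusted p = 0.15 with an estimated correlation), the member being Hlf. Of the erythroid markers, 0 of 6 were higher and 1 lower (1 and 4 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 8.7e-04, adjusted p = 0.34 with an estimated correlation). The list lost its call without old mouse 1 (adjusted p = 0.26). Lymphoid-primed progenitor markers (median -0.04, camera adjusted p = 0.55), lymphoid transcription regulators (median -0.04, camera adjusted p = 0.94), cytokine receptors of lymphoid progenitors (median -0.10, camera adjusted p = 0.37) and V(D)J recombination genes (median 0.21, camera adjusted p = 0.12) did not pass. The V(D)J list passed without young mouse 3 or old mouse 2 (adjusted p = 0.021 and 0.049). In all 7 of 28 lists passed, 0 of them with an estimated correlation or by fry, and 11 without young mouse 3.

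In the other classes of week 8 fewer genes passed. In monocyte-like cells 25 of 9935 genes passed (21 higher, 4 lower), with 9 without young mouse 1, 8 without young mouse 2, 75 without old mouse 1, 16 without old mouse 2, 48 without old mouse 3, 91 with the mouse number as a block and 5 when clustered without genes changed in any class. In conventional dendritic-like cells 17 of 9083 genes passed (8 higher, 9 lower), with 9 without young mouse 1, 7 without young mouse 2, 26 without old mouse 1, 28 without old mouse 3 and 24 with the block. In neutrophil-like cells 17 of 10621 genes passed (7 higher, 10 lower), with 1 without young mouse 1, 28 without young mouse 2, 45 without old mouse 1, 1 without old mouse 3 and 38 with the block. In B-lineage-like cells (3 young and 2 old mice) only Gdf3 passed, with 0 counts in young mice and 27.4 ± 6.19 CPM in old mice, at least 14.0-fold higher from summed counts against a floor of 3 over the group. DESeq2 called 0 genes and 314 had an unadjusted edgeR p under 0.05. Gdf3 did not pass without young mouse 1 (1 gene) or old mouse 2 (9 genes), or after thinning (0 genes). The edgeR count was 2 without young mouse 2, 30 without young mouse 3, 19 without old mouse 1 and 40 with the mouse number as a block. In plasmacytoid dendritic-like cells edgeR called 0 of 10248, 429 having an unadjusted p under 0.05, DESeq2 called 3, and edgeR called 13 without old mouse 1 and 8 without old mouse 3. HSC-like, basophil and mast-like, and T, NK and innate lymphoid-like cells were too few to test.

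Surface proteins at week 8 showed 0 changes past the edgeR threshold over all cells (1 at an unadjusted p under 0.05, 0 by limma) and 0 in multipotent progenitor-like cells (1 at an unadjusted p under 0.05, 0 by limma). CD150 was at 1.24 ± 0.49 over all cells (adjusted p = 0.61), passing without old mouse 2 (1.62, adjusted p = 0.0024). CD117 was at -0.24 ± 0.22 (adjusted p = 0.61), and CD135, the sorted Flt3 protein, had no entry among this week's deposited antibody counts. In multipotent progenitor-like cells CD4 was at -0.92 ± 0.23 (adjusted p = 0.063).

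Whether the age difference itself differed between the weeks was tested as an interaction, in which time point, gate, depletion and library change together. In multipotent progenitor-like cells 65 genes passed. Fos, higher in old mice at week 4 (1.01) and lower at week 8 (-1.43), differed by -2.42 ± 0.36 (week 8 minus week 4). So did Fosb (-2.30 ± 0.37), Rgs1 (-1.80 ± 0.21), Rhob (-1.31 ± 0.17), Jun (-1.24 ± 0.19) and Jund (-1.15 ± 0.16). Hlf differed by -0.89 ± 0.18, and Gdf3 (1.31 ± 0.19) and Mcm5 (0.55 ± 0.12) in the other direction. The mix of clusters ran the way of Rgs1 and Hlf: a cluster led by both took 30.3% of the class in young and 38.6% in old mice at week 4, and another 54.2% and 45.1% at week 8. Averaged over clusters Hlf was at 0.04 and -0.62 (0.10 and -0.79 in the class) and Rgs1 at 0.82 and -0.65 (0.98 and -0.83 in the class). The immediate early and stress list had a median of 0.41 at week 4 and -0.57 at week 8 (camera adjusted p = 4.1e-40, and adjusted p = 0.023 with an estimated correlation).

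Over all cells 3770 genes differed between the weeks in their age effect, in monocyte-like cells 24 and in neutrophil-like cells 16. Over all cells the HSC list had a median of 1.25 at week 4 and 0.04 at week 8 (camera adjusted p = 2.4e-12, adjusted p = 0.29 with an estimated correlation). The multipotent progenitor-like count was 43 without young mouse 2 of week 4, 115 without young mouse 3 of week 4, 133 without old mouse 1 of week 4, 31 without old mouse 2 of week 4, 34 without young mouse 1 of week 8, 35 without young mouse 2 of week 8 and 42 without old mouse 3 of week 8. The monocyte-like count was 11 without young mouse 1 of week 4, 10 without young mouse 2 of week 4, 3 without old mouse 2 of week 4, 15 without young mouse 1 of week 8 and 15 without young mouse 2 of week 8. The neutrophil-like count was 26 without young mouse 3 of week 4, 39 without old mouse 1 of week 4, 8 without young mouse 1 of week 8, 27 without young mouse 2 of week 8, 34 without young mouse 3 of week 8 and 28 without old mouse 1 of week 8.

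**Figure D5:**
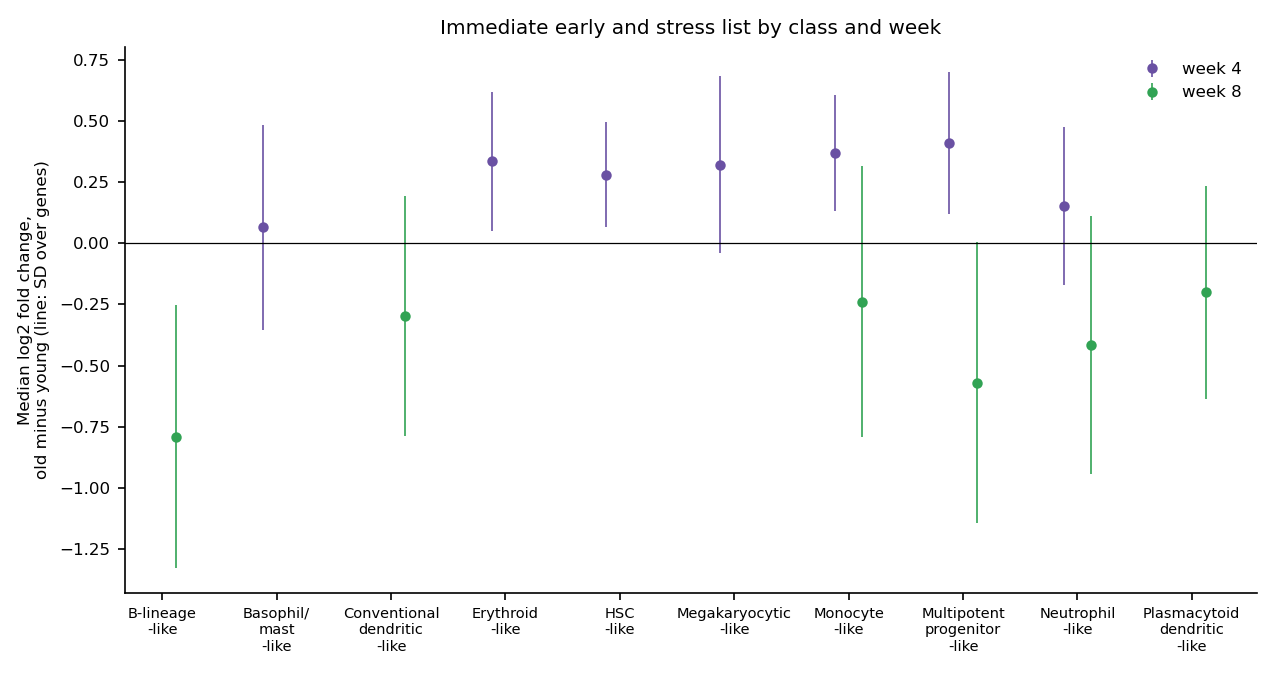
Median log2 fold change with age (old minus young, y axis) of the immediate early and stress list in each tested class (x axis), purple at week 4 and green at week 8; lines are the SD over the list's genes (18 to 24 genes per class). The 7 classes of week 4 lie between 0.07 and 0.41 and the 6 classes of week 8 between -0.79 and -0.20.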

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

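Written after their results were seen were the tests of handling for the immediate early genes, of the splits of the 6 mice within a week, of draws by the ages they kept, and of the HSC list over clusters; the others were written before. Clustering on thinned cells or without genes changed in any class was added after the data had been seen. Groups of 3 mice were not tested for outlying samples.

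At week 4 HSC-like cells took a 5.38-fold higher share of the sorted cells in old mice (log2 fold change 2.43 ± 0.23). Clusters drawn along genes that themselves differ with age are argued against, since clustering without those genes gave a log2 fold change of 2.35 or more. Naming the clusters still used all genes of the marker lists, so that a name given along age-changed genes was not tested. Fewer UMIs per cell in old mice are argued against as the whole cause, since clustering and naming cells thinned to 5000 UMIs gave 2.51. A gate, or a tamoxifen label, that admitted stem cells at another rate in old mice stays open and untested, as does a difference of the stem cell pool with age.

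In multipotent progenitor-like cells immediate early and stress genes had a median of 0.41 at week 4 (5 of 22 higher) and -0.57 at week 8 (2 higher and 11 lower of 22), each called by camera but not with an estimated correlation (adjusted p = 0.096 and 0.15). Another mix of clusters within the class is argued against, since the median averaged over its clusters kept 0.830 of the class's own or more at both weeks. Handling that differed between the ages' mice on each day may contribute: the list's median had the sign of this class in all 13 classes tested (7 of week 4, 6 of week 8), and such genes are known to respond to cell preparation. Time point, gate and pool changed together, so that a biological difference with age between the weeks stays open and untested.

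Megakaryocytic-like cells of week 4 held 1035 genes changed with age, the highest count among the classes of that week, though HSC-like cells held more under the ratio rule (1246 against 908) and with Scrublet-called cells kept (1236 against 1007). Old and young cells lying in different clusters of the class is argued against as the main cause, since over 949 of these genes the log2 fold averaged over clusters was a median 0.734 of the class's own (quartiles 0.574 to 0.892), with the same sign in 933. The classes hold different numbers of cells and UMIs, so that their counts are not comparable as sizes of an age effect. A biological change of these cells with age stays open and untested.

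The age effect differed between the weeks, by the interaction test, for 3770 genes over all cells, 24 in monocyte-like, 65 in multipotent progenitor-like and 16 in neutrophil-like cells. By camera 16, 9, 9 and 6 lists differed in the same order, and 0, 1, 4 and 1 with an estimated correlation. In monocyte-like cells the immediate early and stress list differed by a median of -0.70 (0.37 at week 4, -0.24 at week 8, adjusted p = 5.4e-27, adjusted p = 0.019 with an estimated correlation). In multipotent progenitor-like cells the same list differed by -1.01 (adjusted p = 4.1e-40, adjusted p = 0.023 with an estimated correlation), the HSC list by -0.43 (0.22 and -0.28, though 0.08 and -0.12 averaged over clusters, adjusted p = 5.9e-07, adjusted p = 0.039 with the estimate), the S phase list by 0.35 (-0.10 and 0.24, adjusted p = 1.5e-24, adjusted p = 0.023 with the estimate) and the MHC class II list by -0.16 (0.19 and 0.09, adjusted p = 0.0015, adjusted p = 0.039 with the estimate). In neutrophil-like cells the neutrophil list differed by -0.29 (0.02 and -0.20, adjusted p = 3.6e-11, adjusted p = 0.042 with the estimate). Of 100 draws of the ages within each week, the real one included, 1 gave as many genes in monocyte-like cells (24, highest other 15). In multipotent progenitor-like (65, highest other 53) and in neutrophil-like cells (16, highest other 7) 1 draw did as well. Over all cells 6 did (3770, highest other 4611), but the other 5 kept the real ages of week 4 and so its age effect, while the 77 draws that kept neither week's ages gave 0 genes. The draws there do not decide on chance.

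Within a week the 6 mice make 10 splits, too few for a share under 0.05. The real split gave 6806 genes over all cells of week 4 (highest other 0), 156 in HSC-like (8), 1035 in megakaryocytic-like (1), 107 in monocyte-like (1), 63 in multipotent progenitor-like (2) and 52 in neutrophil-like cells (6). Erythroid-like cells gave 0, so that all 10 gave as many, and the split of young 1, old 1 and old 2 against the rest gave 90, which points to a structure of the samples. At week 8 the real split gave 5 over all cells (0 in each other, those that also part all 3 same-numbered pairs included), 17 in conventional dendritic-like (5), 25 in monocyte-like (0) and 61 in multipotent progenitor-like cells (10). In neutrophil-like cells it gave 17 and 2 splits gave as many, young 1, young 2 and old 1 against the rest giving 20. In plasmacytoid dendritic-like cells it gave 0 (3).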

How the results depend on the processing

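The settings without HSC-like cells, clustered without genes changed in any class, clustered on thinned cells and named by pooled CPM (the first form) were chosen after seeing the data. The HSC-like, erythroid-like and monocyte-like shares of week 4 kept their direction and their side of the threshold under every alternative run, with a log2 fold change of 2.00 to 3.41 for HSC-like cells. Over all alternatives, 217 values of the results that answer a comparison stayed close and 74 moved; among other results 7800 kept direction and side of the threshold or moved little, 452 lost a call, 149 gained one, 115 counts or values moved and 14 reversed. RLE in place of TMM shifted the median gene of all cells at week 4 from 0.02 to 0.01 and split the changed genes into 3373 higher and 3452 lower. Depth limits HSC-like cells of young mice, of which 278 were found. Where not said otherwise, the cause of a change was not tested.

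Of the 156 genes in HSC-like cells, no filter on low counts gave 316 (all 156 among them), the ratio rule for hashtags 1246 (130 shared), the stricter cell filter 55 (47), Scrublet-called cells kept 1236 (130), thinned cells 102 (86) and clustering on thinned cells 99 (85). All cells of week 4 gave 6806 genes, against 4377 after thinning, which removes UMIs, and 3510 without HSC-like cells. All cells of week 8 gave 5, against 33 with DESeq2, 50 with no filter, 27 with the mouse number as a block and 0 after thinning. The classes of week 4 together held 1451 changed genes, against 819 with DESeq2, 2706 with no filter, 2406 with the ratio rule, 2558 with Scrublet-called cells kept, 571 after thinning and 456 when clustered on thinned cells. Those of week 8 held 121, against 664 with no filter, 267 with the block and 76 with the stricter filter. The count of classes changed in share at week 8 went from 0 to 1 with the block (HSC-like, higher), with Scrublet-called cells kept (basophil and mast-like, lower) and when clustered without genes changed in any class (basophil and mast-like, lower). HSC-like proteins went from 0 to 3 with limma and 2 with the ratio rule.

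An estimated correlation took the lists called from 19 to 0 in all cells of week 4, from 12 to 1 in HSC-like cells and from 13 to 0 in all cells of week 8, and fry gave 2 in HSC-like cells and 0 in all cells of week 8. Interaction counts rose with DESeq2 to 42 in monocyte-like, 141 in multipotent progenitor-like and 63 in neutrophil-like cells, and with no filter to 196, 222 and 151.

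Reversed were Prss34 in all cells of week 4 (0.13 under the ratio rule), Mllt3 and Tubb4b in HSC-like cells (0.0491 and -0.0601 under the ratio rule, 0.0455 and -0.10 with Scrublet-called cells kept), Sox4 in HSC-like cells (0.08 with the stricter filter), Elane in multipotent progenitor-like cells of week 8 (-0.58 when clustered without genes changed in any class) and the unnamed share of week 4 (-1.42 when clustered on thinned cells). Scored 1 for up and -1 for down, list directions turned without old mouse 1 in all cells of week 8 for plasmacytoid dendritic (to 1) and ribosome biogenesis (to -1), without old mouse 2 for HSC (to 1) and without old mouse 3 for G2 and M phase (to 1), and in multipotent progenitor-like cells of week 4 for G2 and M phase without young mouse 1 (to -1) and interferon response without old mouse 3 (to -1).

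Leaving out each mouse gave ranges of 5230 to 6666 genes in all cells of week 4, 83 to 158 in HSC-like cells, 1 to 43 in all cells of week 8, 782 to 1527 over the classes of week 4 and 62 to 253 over those of week 8. The share counts ranged from 3 to 4 and 0 to 1, the log2 fold change of the share from 2.29 to 2.54 for HSC-like, -1.70 to -1.46 for erythroid-like and -1.53 to -1.34 for monocyte-like cells. Proteins called ranged from 11 to 16 at week 4, 0 to 7 in HSC-like cells and 0 to 1 at week 8, and lists from 14 to 18, 9 to 13 and 6 to 17 in all cells of week 4, HSC-like cells and all cells of week 8. Interaction counts ranged from 2646 to 3958 over all cells, 3 to 28 in monocyte-like, 31 to 133 in multipotent progenitor-like and 8 to 39 in neutrophil-like cells. Among these, monocyte-like cells gave 10 without young mouse 2 of week 4 and 15 without young mouse 1 or 2 of week 8, multipotent progenitor-like cells 34 and 35 without young mouse 1 and 2 of week 8, and neutrophil-like cells 26 and 34 without young mouse 3 of week 4 and week 8.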

Other observations

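CD3 tags per cell were highest in mice of the same 3 hashtags at both weeks, as were those of the isotype control and, at week 4, of CD135. At week 4 they were 6.16 in young 1, 6.49 in old 1 and 7.03 in old 2, against 2.22, 2.91 and 3.82 in young 2, young 3 and old 3. At week 8 they were 3.49, 4.09 and 4.25 in the first 3, against 1.34, 1.85 and 1.84. No test was run.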
